A study of Homo sapiens with 10 samples.

How the data were processed

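Total RNA from RD rhabdomyosarcoma cells was made into stranded mRNA libraries in the authors' laboratory, per the labels' protocols, for 5 groups of 2 replicates. The groups were nonspecific siRNA, NRAS siRNA 1 and NRAS siRNA 2, each at 10 nM with collection at 48 h, and DMSO and the ERK inhibitor SCH772984 at 300 nM with collection at 24 h. The labels spell the drug in more than 1 way, and the spelling SCH772984 was used. Groups and replicate numbers were taken from the sample titles.

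The deposited values are whole-number counts of reads per gene, not normalised, and the submitters' processing notes name bcl2fastq, TopHat2, SAMtools and HTSeq with the builds hg19 and GRCh37. Versions, the gene annotation and the strand setting of the counting step are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The 10 deposited count files were identical to the 10 columns of the deposited series table. In each file 5 category lines that name no gene were left out of library sizes and tests. Reads without a gene made up 9.91 to 11.3% of the reads in a library, reads without a unique alignment 27.0 to 28.9% and ambiguous reads 0.591 to 0.649%, together 38.3 to 39.4%. Multiply aligned reads are therefore missing from gene totals, which lowers the counts of genes with near-identical copies. The files pair counts with gene symbols and hold no coordinates, and the reference used here is of another build, so no positions in the genome are given.

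Library totals over genes ran from 23224063 to 30768970 counts. At this depth 3 counts, used as the floor for a gene at 0, correspond to 0.0952 to 0.132 CPM. Replicates of a group had Pearson's r of 0.990 to 0.993 on log2 CPM across genes. A chi-square comparison of their counts gave 13.2 to 25.5 times its degrees of freedom in each group, so no pair matched within sampling noise and every library was counted as 1 replicate. The common biological coefficient of variation was 0.115, and TMM factors lay between 0.968 and 1.03.

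Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest) on counts as deposited, with TMM scaling and filterByExpr by group at a minimum count of 10. All 10 libraries entered 1 fit with 5 residual degrees of freedom and no covariate. Adjustment was by Benjamini-Hochberg over 14761 tested genes, with a threshold of 0.05. The comparisons were each NRAS siRNA and the mean of both against the nonspecific siRNA, the ERK inhibitor against DMSO, siRNA 1 against siRNA 2, the nonspecific siRNA against DMSO, and the interaction, the mean siRNA response minus the ERK inhibitor response. Log2 fold changes are those of edgeR, with standard errors derived from the same fit. For genes with very few counts in a group the ratio of summed counts is given with its exact counting interval at 95% confidence.

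Gene lists, 33 in number of which 32 had at least 3 tested members, were written before the data were examined, as were the tests, the alternatives and the rule for named genes. They cover ERK output, muscle, cell cycle, cell death, matrix, metabolism, stress and markers of other cell types. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the residuals, and with fry. The number of members past the threshold is given over all genes tested and adjusted over the list alone.

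The rule for named genes took NRAS, HRAS and further genes of ERK signalling, muscle and cell cycle fixed by name. To these it added the 5 greatest rises and 5 greatest falls among genes past the threshold, with treated libraries on 1 side of both control libraries and a mean of at least 5 CPM in the higher group. Up to 4 members past the threshold were added from each list with a call or at least 3 such members. For the interaction the 5 highest and 5 lowest differences were taken, and for siRNA 1 against siRNA 2 the 3 highest and 3 lowest. The rule gave 94 genes for the NRAS comparison and 137 for the ERK inhibitor, of which the text names a part, and some are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

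Both NRAS comparisons share their control libraries, so the correlation that shared controls give was measured in 20 simulations of unchanged groups against those controls. For 3' UTR sequences, 12432 of 14761 tested genes (84.2%) were matched by symbol to a human reference annotation of a later build, and 12408 entered a scan of 16239 7-mers, each carried by at least 50 genes. Log2 fold changes, clipped at 1.5, were first regressed on log2 length and the share of G and C bases of the 3' UTR, with their squares and product. The residuals were ranked, and z measured how far the ranks of genes with a 7-mer departed from the mean rank. For the spread of the highest absolute z, ranks were permuted over genes 200 times. The scan used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the figures used matplotlib 3.10.9.

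The procedures were tested on simulated data, with counts for the 14761 genes drawn from the measured means and library sizes and 200 genes changed 1.5-, 2- or 4-fold. For the mean of both siRNAs 44.8%, 80.6% and 98.5% of these were recovered, for the ERK inhibitor 31.3%, 76.1% and 90.9%, for siRNA 1 34.3%, 85.1% and 95.5%, for siRNA 2 23.9%, 80.6% and 95.5%, and for the interaction 2.99%, 50.7% and 87.9%. False calls were 17 of 166 for the mean of both siRNAs, 14 of 146 for the ERK inhibitor, 14 of 157 for siRNA 1, 13 of 146 for siRNA 2 and 5 of 99 for the interaction, which is above the nominal share for most of these. On a simulated ERK inhibitor comparison edgeR recovered 120 of 200 genes with 15 false calls, DESeq2 134 with 25 and limma-voom 120 with 14. Shifted lists were recovered in 4 of 4 cases with 1 false call among 188 list tests, and planted 7-mers ranked first in 10 of 10 cases. The simulated genes varied independently of each other. In the data the estimated correlation within a list reached 0.934, for NF-kB and cytokines with the mean of both siRNAs. The simulated rate of false list calls therefore does not cover lists whose members vary together.

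Alternatives, each changed alone, were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no expression filter, a filter of 50 counts in 2 libraries, a fit of only the groups compared, the replicate number as a block, an added limit of 1 on the absolute log2 fold change, the estimated correlation and fry for lists, and leaving out each of the 10 libraries in turn. Where this left a group with 1 library, the lone library was assumed to vary like the other groups.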

Results

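RNA was measured in RD cells, a human line grown from a rhabdomyosarcoma, a soft tissue tumour that carries features of developing skeletal muscle. Cells were transfected at 10 nM with a nonspecific siRNA or with 1 of 2 independent siRNAs against NRAS, the gene of a small GTPase upstream of the RAF, MEK and ERK kinases, and collected at 48 h. Other cells were given 300 nM SCH772984, an inhibitor of the ERK kinases, or its vehicle DMSO and collected at 24 h. The design thus asks which transcripts depend on NRAS, which depend on ERK activity, and how far both sets coincide. Each of the 5 groups held 2 libraries, 10 in all, with 23224063 to 30768970 counts assigned to genes per library. Of 23228 genes listed, 14761 were tested and 3022 had no count in any library. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The first principal component held 51.0% of the variance and set the ERK inhibitor libraries apart from the rest.

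NRAS itself was measured at 246 ± 36.8 CPM (SD, n = 2) with the nonspecific siRNA, where CPM are counts scaled to library size. It stood at 52.3 ± 0.166 CPM with siRNA 1 and at 49.5 ± 2.14 CPM with siRNA 2 (SD, n = 2 each). The log2 fold change was -2.23 (SE 0.12) for siRNA 1 and -2.31 (SE 0.12) for siRNA 2, with adjusted p = 4.77e-05 and 5.15e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The transcript thus remained at 21.3% and 20.1% of its control level. In DMSO libraries NRAS stood at 276 ± 9.37 CPM and with the ERK inhibitor at 257 ± 30.8 CPM (SD, n = 2 each), a log2 difference of -0.10 (SE 0.12, edgeR adjusted p = 0.555). HRAS stood just outside the threshold with the siRNAs, at -0.45 (SE 0.12, edgeR adjusted p = 0.0519), and just inside it with the ERK inhibitor, at -0.43 (SE 0.15, adjusted p = 0.0497).

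Knockdown of NRAS lowered genes that ERK signalling is known to induce. DUSP6, a phosphatase that switches ERK off, fell from 239 ± 46.5 CPM to 98.2 ± 2.25 CPM with siRNA 1 and to 105 ± 5.03 CPM with siRNA 2 (SD, n = 2 each). Averaged over both siRNAs, its log2 fold change was -1.24 (SE 0.14), beside -1.19 (SE 0.13) for the feedback inhibitor SPRY4, -0.90 (SE 0.16) for the ETS transcription factor ETV4 and -1.76 (SE 0.22) for the immediate-early factor EGR1. VCAM1, an adhesion molecule, rose from 4.30 ± 1.11 CPM to 15.5 ± 4.17 CPM with siRNA 1 and to 25.0 ± 11.6 CPM with siRNA 2 (SD, n = 2 each). Among genes of at least 5 CPM in the higher group that both siRNAs moved past the threshold, the other greatest rises were those of DKK2, a secreted WNT regulator, at 2.12 (SE 0.35), SEMA3D, a semaphorin, at 1.99 (SE 0.26), ADAMTS9, a matrix protease, at 1.94 (SE 0.20), and KAL1, a secreted matrix protein, at 1.87 (SE 0.20). Besides NRAS and EGR1, the greatest falls among such genes were those of SERPINA3, a protease inhibitor, at -1.82 (SE 0.31), SIGLEC15, a sialic acid receptor, at -1.78 (SE 0.23), and VGF, a neuropeptide precursor, at -1.65 (SE 0.18). CCND1, which encodes cyclin D1, fell by 0.75 (SE 0.20) close to the threshold, with edgeR adjusted p = 0.0482. BCL2L11, which encodes the cell death protein BIM, rose by 0.65 (SE 0.12, edgeR adjusted p = 0.0156). MYC at -0.56 (SE 0.19), FOSL1 at -1.23 (SE 0.50), CDKN1A at -0.87 (SE 0.30), ETV5 at -0.24 (SE 0.13) and MKI67 at -0.12 (SE 0.08) did not pass. Nor did the muscle genes MEF2C at 0.16 (SE 0.15) and MYH3 at -0.11 (SE 0.18), the cell cycle inhibitor CDKN1C at 0.11 (SE 0.24) or the receptor ERBB3 at 0.21 (SE 0.22). MET, a receptor tyrosine kinase, rose by 1.34 (SE 0.17), but was also lower in nonspecific siRNA than in DMSO libraries, at -1.09 (SE 0.19).

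For the mean of both siRNAs edgeR called 438 genes higher and 736 lower, of which 115 and 97 changed at least 2-fold. Separately, siRNA 1 gave 132 higher and 173 lower genes, and siRNA 2 gave 382 higher and 567 lower. These counts lean on single libraries: the total of 1174 became 131 without replicate 1 of the nonspecific siRNA, 402 without its replicate 2, 402 without replicate 1 of siRNA 1 and 377 without replicate 1 of siRNA 2. With DESeq2, siRNA 1 and siRNA 2 gave 763 and 1651 genes, and with a fit of only the groups compared 45 and 225, with 425 for the mean. The replicate number as a block gave 1280 and 2815, with 2846 for the mean, though the labels do not say that numbers pair libraries.

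Of the 32 gene lists that could be tested, 7 passed camera with a preset correlation for the mean of both siRNAs, all of them lower, and 25 did not pass; with a correlation estimated from the residuals camera called 0 lists, with 1 at an unadjusted p under 0.05. In the ERK pathway output list, 15 of 28 tested members fell over all genes tested and 20 when adjusted over the list alone, with none higher, a median log2 fold change of -0.72 and a camera adjusted p of 5.54e-19, but adjusted p = 0.166 with an estimated correlation. DUSP4, a further ERK phosphatase, fell by 1.27 (SE 0.18) in this list. Among immediate-early genes 9 of 20 fell, 12 adjusted over the list alone, including NR4A2 at -1.26 (SE 0.18) and EGR3 at -1.29 (SE 0.33); the median was -0.58 and the camera adjusted p 9.24e-10, but adjusted p = 0.681 with an estimated correlation, as for each of the 5 lists that follow. In the DNA replication list 7 of 40 members fell, 29 adjusted over the list alone with 1 higher, such as MCM7 at -0.50 (SE 0.12) and POLE2 at -0.56 (SE 0.12), with a median of -0.33 and a camera adjusted p of 2.32e-09, lost with an estimated correlation. MYC targets and ribosome biogenesis had 4 of 32 lower, 5 adjusted over the list alone, among them MYBBP1A at -0.64 (SE 0.14), with camera adjusted p = 4.08e-07, lost likewise. Glycolysis and hypoxia had 7 of 27 lower, 13 adjusted over the list alone with 1 higher, among them PFKP, a phosphofructokinase, at -0.94 (SE 0.16), with camera adjusted p = 0.000157, lost likewise. The NF-kB and cytokine list passed at camera adjusted p = 0.0169 with 1 of 17 members lower, the cytokine IL1A, and 2 adjusted over the list alone, and was lost likewise. Mitosis genes passed at camera adjusted p = 0.0174 with 2 of 35 lower, AURKB at -0.49 (SE 0.09) and INCENP at -0.45 (SE 0.09), and 2 adjusted over the list alone, and were lost likewise. Fry, which tests only whether the members of a list move one way on balance, called 5 lists, 4 of them among these 7 and the other that of blood and endothelial cell markers, lower with a median of -0.67 over 6 tested members (fry adjusted p = 0.0257, camera adjusted p = 0.165).

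Both siRNAs moved many of the same genes. Among the calls made separately, 119 genes were higher and 121 lower with both, 240 in all, against 3.42 and 6.65 for independent lists of these lengths, and 1 gene was called in opposite directions. The replicate number as a block gave 1028 genes changed in the same direction by both siRNAs. Both comparisons use the same 2 nonspecific libraries. Across genes, which are not independent replicates, the log2 fold changes of both siRNAs had Pearson's r = 0.812 and Spearman's rho = 0.782, where 20 simulations of unchanged siRNA groups against these controls gave r = 0.525 on average. The covariance was 0.146 against a simulated 0.0395, a difference of 0.106. The 2 control libraries were not split between both comparisons, so part of the excess may come from the shared controls. Without replicate 1 of siRNA 1 the overlap was 27 genes, and without replicate 1 of siRNA 2 it was 32.

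A direct test between both siRNAs found 34 genes higher and 29 lower with siRNA 1 than with siRNA 2. CDCA4, BTG3 and TMEM55A were higher with siRNA 1, at log2 differences of 1.52 (SE 0.11), 1.45 (SE 0.15) and 1.33 (SE 0.14). C9orf6 at -2.48 (SE 0.13), KLF2, an endothelial transcription factor, at -1.38 (SE 0.20) and DOK4, an adaptor of receptor kinases, at -1.26 (SE 0.11) were lower. NRAS did not differ detectably between both siRNAs, at 0.08 (SE 0.12, edgeR adjusted p = 0.963). The count of 63 genes depends on each siRNA library, and fell to 6 without replicate 2 of siRNA 1 and 6 without replicate 1 of siRNA 2.

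**Figure D1:**
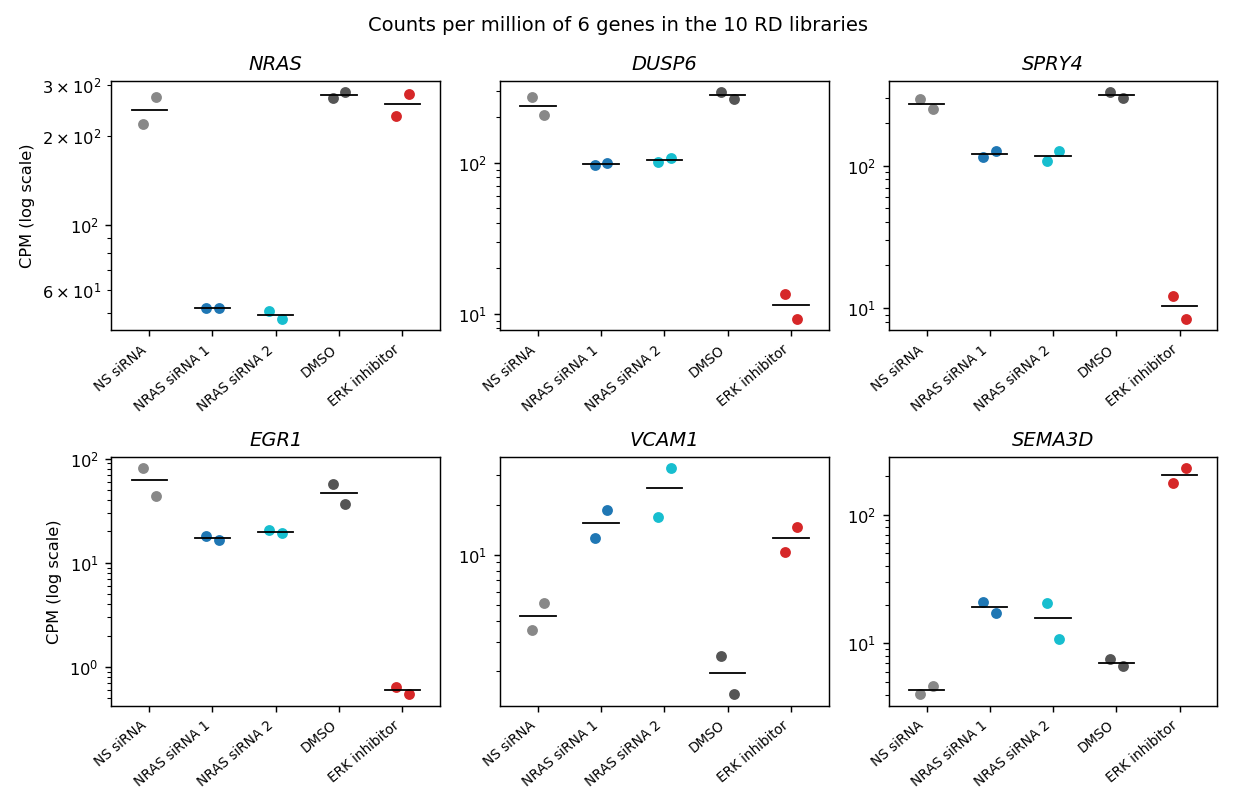
CPM on a log axis for NRAS, DUSP6, SPRY4, EGR1, VCAM1 and SEMA3D in each of the 10 libraries; points are libraries and bars are means of 2. NRAS stood near 52.3 and 49.5 CPM with its siRNAs and at 257 CPM with the ERK inhibitor, whereas DUSP6 was lower with the ERK inhibitor, at 11.4 CPM, than with either siRNA.

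The ERK inhibitor changed more genes and by larger amounts. DUSP6 fell from 278 ± 19 CPM in DMSO to 11.4 ± 3.02 CPM, SPRY4 from 313 ± 18.5 CPM to 10.3 ± 2.70 CPM, and ETV4 from 264 ± 7.14 CPM to 5.97 ± 1.94 CPM (SD, n = 2 each). Their log2 fold changes were -4.61 (SE 0.19), -4.92 (SE 0.19) and -5.47 (SE 0.24). ETV5 fell by 3.83 (SE 0.17), EGR1 by 6.29 (SE 0.39), FOSL1, a partner in the AP-1 factor, by 3.42 (SE 0.69), and CCND1 by 1.72 (SE 0.24). MYEOV had 5 counts over both treated libraries and 307 over both DMSO libraries, a ratio of 69.6 in favour of DMSO with a counting interval of 29.5 to 216. SERPINA3 fell by 4.74 (SE 0.57). Among the genes that rose, IBSP, which encodes bone sialoprotein, had 1212 counts with the inhibitor and 6 in DMSO, a ratio of 178 with a counting interval of 81.7 to 487. DCN, which encodes the matrix proteoglycan decorin, had 319 and 2 counts, a ratio of 141 (interval 38.7 to 1168), and the growth factor IGF1 had 294 and 2 counts, a ratio of 130 (35.6 to 1076). For CRYAB, a small heat shock protein of muscle and lens, 317 and 3 counts gave a ratio of 93.3 (31.6 to 455). These 95% intervals, like the floors given for genes near 0, cover counting error only. PDE11A, a phosphodiesterase, rose from 0.702 ± 0.189 CPM to 57.5 ± 6.17 CPM (SD, n = 2 each).

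MKI67, a marker of cycling cells, fell by 0.72 (SE 0.09, edgeR adjusted p = 0.000496). CDKN1C, an inhibitor of cyclin-dependent kinases, rose by 1.34 (SE 0.29, edgeR adjusted p = 0.00707) and BCL2L11 rose by 0.65 (SE 0.14, adjusted p = 0.00802). MYC at -0.05 (SE 0.23), CDKN1A at -0.93 (SE 0.37), ERBB3 at -0.60 (SE 0.28), MEF2C at 0.30 (SE 0.18) and MYH3 at -0.34 (SE 0.20) did not pass. edgeR called 1948 genes higher and 2180 lower, of which 827 and 409 changed at least 2-fold; upper-quartile scaling turned this balance, to 2210 higher and 1725 lower. The total of 4128 became 1924 without replicate 2 of DMSO and 1875 without replicate 1 of the ERK inhibitor.

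For the ERK inhibitor 13 of 32 lists passed camera with the preset correlation, 7 lower and 6 higher, and 19 did not. In the ERK pathway output list 23 of 28 members fell and 1 rose, with the same counts adjusted over the list alone, a median of -1.75 and a camera adjusted p of 7.82e-40. Mitosis genes fell in 27 of 35 cases, 28 adjusted over the list alone, including KIF2C at -0.86 (SE 0.10), AURKA at -0.82 (SE 0.10) and FOXM1 at -0.80 (SE 0.10); the median was -0.60 and the camera adjusted p 3.52e-13. These were the 2 lists that passed both ways, with adjusted p = 0.0327 and 0.0486 with an estimated correlation. DNA replication genes fell in 31 of 40 cases, 38 adjusted over the list alone, such as CDC45 at -1.08 (SE 0.16), with camera adjusted p = 3.52e-13 but adjusted p = 0.446 with an estimated correlation.

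Among lists that moved upward, cholesterol synthesis had 16 of 24 members higher and none lower, the same adjusted over the list alone, with HMGCS1 at 1.14 (SE 0.12) and MVD at 1.15 (SE 0.16); the camera adjusted p was 7.10e-08, and adjusted p = 0.300 with an estimated correlation. The list of smooth muscle, fat and bone markers had 8 of 14 higher and 2 lower, the same adjusted over the list alone, with a median of 1.06, a camera adjusted p of 9.64e-07 and adjusted p = 0.0623 with an estimated correlation. Its higher members were of smooth muscle as well as bone, such as ACTA2 at 3.88 (SE 0.41), LMOD1 at 3.12 (SE 0.46) and the transcription coactivator MYOCD, with 163 counts against 5 and a ratio of 28.8 (12.1 to 89.8). Collagen and matrix genes had 9 of 21 higher and 3 lower, 10 and 4 adjusted over the list alone, with LUM at 3.32 (SE 0.27), COL12A1 at 2.54 (SE 0.14) and COL5A1 at 1.98 (SE 0.12); the camera adjusted p was 9.64e-07, and adjusted p = 0.110 with an estimated correlation. Sarcomere genes had 13 of 27 higher and 1 lower, 16 and 2 adjusted over the list alone, led by TNNI1 at 5.70 (SE 0.33), a slow troponin, and TNNC1 at 3.55 (SE 0.27). MYL4, an embryonic myosin light chain, had 106 counts against 2, a ratio of 46.8 (12.6 to 391), and cardiac actin ACTC1 had 66 against 5, a ratio of 11.7 (4.75 to 37.1). This list had camera adjusted p = 4.17e-06 and adjusted p = 0.106 with an estimated correlation. Myogenic differentiation factors had 4 of 13 higher and none lower, 5 adjusted over the list alone, among them the muscle cadherin CDH15 at 3.54 (SE 0.44) and the splicing factor RBM24 at 1.31 (SE 0.24), with camera adjusted p = 0.00314 and adjusted p = 0.300 with an estimated correlation. Receptor tyrosine kinases and their adaptors had 8 of 20 higher and 2 lower, 9 and 2 adjusted over the list alone, such as PDGFRB at 1.26 (SE 0.13) and FGFR3 at 1.52 (SE 0.16), with camera adjusted p = 0.0231 and adjusted p = 0.319 with an estimated correlation.

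Of the remaining lists with lower medians, MYC targets and ribosome biogenesis had 14 of 32 lower, 22 adjusted over the list alone, with camera adjusted p = 3.44e-05 and adjusted p = 0.722 with an estimated correlation. Immediate-early genes had 8 of 20 lower and 2 higher, 10 and 2 adjusted over the list alone, with FOS at -1.69 (SE 0.23), camera adjusted p = 0.000969 and adjusted p = 0.542 with an estimated correlation. Glycolysis and hypoxia had 12 of 27 lower and 3 higher, 12 and 4 adjusted over the list alone, with LDHA at -0.99 (SE 0.09) and the glucose transporter SLC2A3 at -1.20 (SE 0.10), camera adjusted p = 0.00276 and adjusted p = 0.450 with an estimated correlation. SLC2A3 was also higher in nonspecific siRNA than in DMSO libraries, by 1.04 (SE 0.09). Ribosomal protein genes had 8 of 31 lower, 9 adjusted over the list alone, with camera adjusted p = 0.0230 and adjusted p = 0.784 with an estimated correlation; their many pseudogenes make these counts uncertain.

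**Figure D2:**
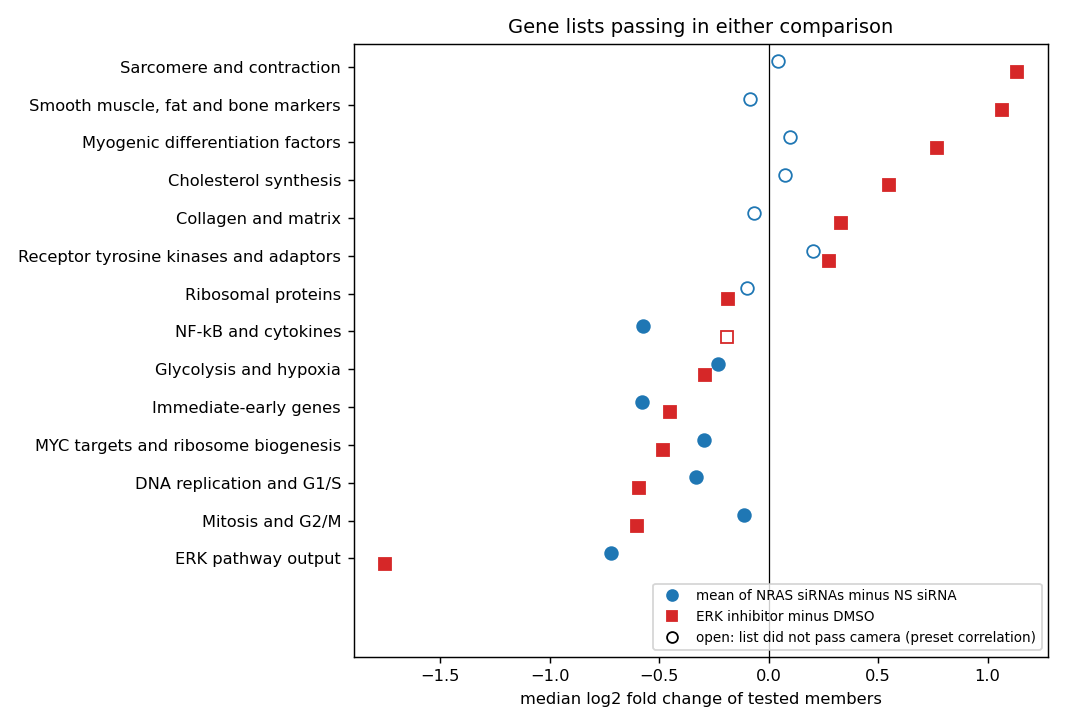
Median log2 fold change of the tested members for each gene list that passed camera in at least 1 comparison; circles are the mean of the NRAS siRNAs minus the nonspecific siRNA, squares the ERK inhibitor minus DMSO, and open symbols did not pass. The ERK pathway output list had the lowest medians, -0.72 and -1.75.

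Regulators of the muscle lineage were near or below the counting floor of 3 counts per library, which equals 0.0952 to 0.132 CPM here. MYOD1, a master regulator of muscle fate, had 0 to 5 counts per library and 25 over all 10, MYOG had 0 to 3 and 10 over all, and PAX7, a satellite cell factor, had 1 to 6 and 34 over all. MYF5 had 0 counts in every library and the myosin gene MYH8 had 1 count over all 10. No direction can be given for these genes at this depth. Other genes of the lineage, of which DES and PAX3 were chosen after their values were seen, were present: DES, which encodes the intermediate filament desmin, stood at 22.1 ± 3.41 CPM in DMSO libraries (SD, n = 2), PAX3 had 258 to 393 counts per library and MEF2C 781 to 1374. Among 56 sarcomere genes in the files, 12 reached 1 CPM in DMSO libraries. MSC, which encodes the bHLH repressor musculin, rose by 4.17 (SE 0.32) with the ERK inhibitor.

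Set side by side, the responses to NRAS knockdown and to the ERK inhibitor shared a direction in many genes and differed in size. Of the genes called by each, 268 were higher in both and 390 lower in both, against 57.8 and 109 for independent lists, and 36 were called in opposite directions. With calls required from each siRNA separately, 76 genes were higher and 97 lower in all 3 comparisons, 173 in total, against 15.7 and 17.9. These comparisons share no library. Across genes, the log2 fold changes had Pearson's r = 0.541 and Spearman's rho = 0.451, and r = 0.716 over the 4128 genes called with the ERK inhibitor. Without an expression filter the correlation was 0.189. In both, 6 gene lists passed camera in the same direction with the preset correlation, and 0 with an estimated correlation. The total of 173 was 18 without replicate 1 of siRNA 1 and 19 without replicate 1 of siRNA 2.

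The interaction test, which asks whether the response to NRAS siRNA differs from the response to the ERK inhibitor, called 403 genes with a higher and 675 with a lower difference. ETV4 at 4.57 (SE 0.29), EGR1 at 4.53 (SE 0.47), MYEOV at 4.48 (SE 0.60), SPRY4 at 3.73 (SE 0.22) and ETV5 at 3.59 (SE 0.22) had the highest differences under the same expression limit, lying further below control with the drug than with the siRNAs; ETV5 did not pass with the siRNAs alone. IBSP at -5.84 (SE 1.00), DCN at -5.63 (SE 1.09), PDE11A at -4.85 (SE 0.54), ELN, which encodes elastin, at -4.57 (SE 0.53) and TNNI1 at -4.43 (SE 0.77) had the lowest differences under that limit. Those of IBSP and DCN rest on 6 and 2 counts in DMSO libraries and on 4 and 6 in nonspecific siRNA libraries, where TNNI1 had 7. Of the 1078 genes, 922 were also called with the ERK inhibitor. Among these, 481 had log2 fold changes of the same sign in both comparisons and of larger size with the inhibitor. This count required no call with the siRNAs, so it does not show that each of these genes responded to them. TGFB2 rose by 1.12 (SE 0.15) with the siRNAs and 1.18 (SE 0.17) with the inhibitor, a difference of -0.06 (SE 0.22). BCL2L11 likewise had a difference of 0.00 (SE 0.19). MET rose with the siRNAs and stood at 0.34 (SE 0.18) with the inhibitor, and its difference of 1.00 (SE 0.24) passed with edgeR adjusted p = 0.0378. As MET was also lower in nonspecific siRNA than in DMSO libraries, this difference may belong in part to the control. For lists, 11 passed camera, with the lowest p for the ERK pathway output list (median 0.97), collagen (-0.60) and mitosis (0.45), and 0 passed camera with an estimated correlation, where 5 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0587. Fry called 10 lists, 8 of them among these 11. Without replicate 1 of the ERK inhibitor the count of 1078 was 343, and without replicate 2 of DMSO it was 359.

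**Figure D3:**
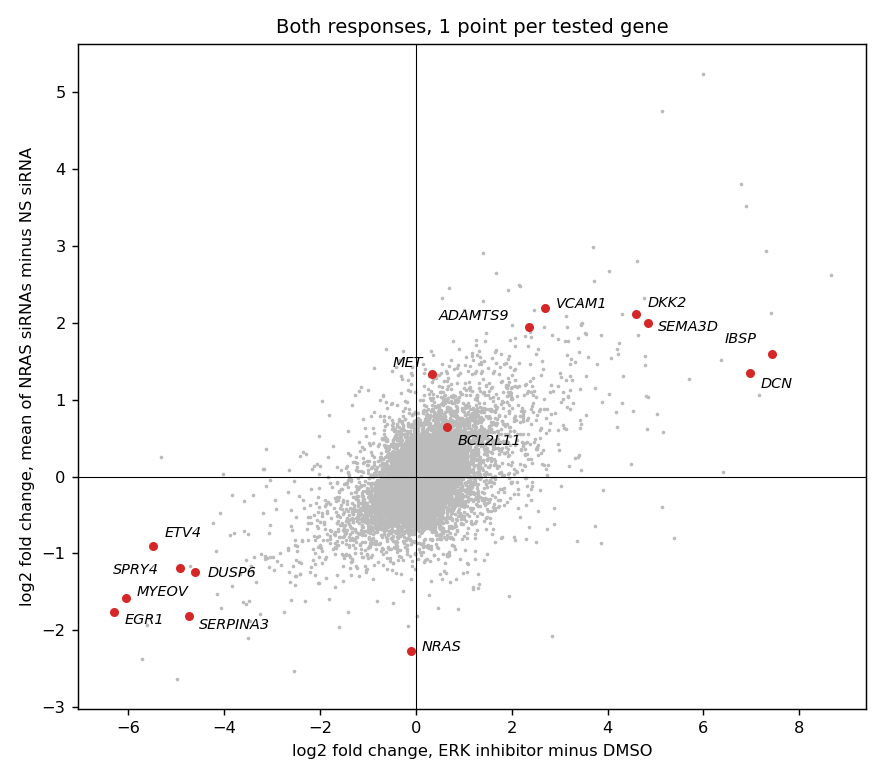
Log2 fold change with the ERK inhibitor (horizontal) against that with the mean of the NRAS siRNAs (vertical), 1 point for each of 14761 tested genes, with named genes in red. NRAS lies at -2.27 on the vertical and -0.10 on the horizontal axis, and EGR1 at -1.76 and -6.29.

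The control groups, nonspecific siRNA and DMSO, differed in transfection, siRNA, vehicle and time of collection at once. Between them 40 genes were higher and 16 lower with the nonspecific siRNA. Examples chosen after their values were seen were BTG2, an antiproliferative gene, at 1.21 (SE 0.18), MSRB3, a methionine sulfoxide reductase, at -1.19 (SE 0.10) and TOMM20, a mitochondrial import receptor, at -0.94 (SE 0.09). The count of 56 ranged from 6 to 31 as single libraries were left out.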

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

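Of the tests below, those of the muscle regulators, the first scan of 7-mers and the comparison of transfection and collection time were chosen only after the result was seen, as was the choice of the 7-mer TGACGTA; the others were set before their result was known.

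Several results drew attention because a direct test found that groups responded differently. Between both siRNAs against the same target 63 genes differed, with CDCA4 at 1.52, BTG3 at 1.45 and TMEM55A at 1.33 higher, and C9orf6 at -2.48, KLF2 at -1.38 and DOK4 at -1.26 lower with siRNA 1. Between the responses to NRAS siRNA and to the ERK inhibitor 1078 genes differed. Among genes with at least 5 CPM in the higher group, the highest log2 differences were those of ETV4 at 4.57, EGR1 at 4.53, MYEOV at 4.48, SPRY4 at 3.73 and ETV5 at 3.59, and the lowest those of IBSP at -5.84, DCN at -5.63, PDE11A at -4.85, ELN at -4.57 and TNNI1 at -4.43. Those of IBSP, DCN and TNNI1 rest on few counts in the control libraries. Among the 36 genes called in opposite directions, which were selected for such a difference, examples chosen after their values were seen were the collagen gene COL1A1, at -0.38 with the siRNAs and 1.34 with the inhibitor, and the semaphorin SEMA3C, at 0.68 and -0.60.

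The siRNA differences went with short sequences in 3' UTRs. Genes carrying GACTATA ranked lower with siRNA 1 than with siRNA 2 (z = -11.2) and genes carrying ACCTAAG ranked lower with siRNA 2 (z = 10.4). The permuted highest absolute z reached 4.78, and p = 0.00498 is the smallest that 200 permutations can give. These ranks are adjusted for 3' UTR length and base content, and plain medians moved little. For siRNA 1 minus siRNA 2 they were -0.109 with GACTATA and 0.00443 without, and 0.0194 with ACCTAAG and -0.00359 without. For siRNA 2 against the nonspecific siRNA they were -0.00653 with ACCTAAG and -0.00798 without. Among called genes with a 3' UTR in the scan the link was closer. Of those lower with siRNA 1 than with siRNA 2, 17 of 27 carried GACTATA, 63.0% against 7.13% of all genes scanned. Of those lower with siRNA 2, 17 of 29 carried ACCTAAG, 58.6% against 7.68%. The 7-mers were picked from this same comparison, so these shares are no independent support. Both 7-mers occur in the NRAS transcript (2 of 2), although 20.9% of sampled 7-mers and TGACGTA do too, so that this test is weak. Seed-matched silencing of unintended transcripts is a candidate explanation that both z values fit. The siRNA sequences were not used here, however, and no biological explanation was tested. Genes carrying TGACGTA ranked lower with the nonspecific siRNA than in DMSO (z = -7.67) and higher with the NRAS siRNAs than with the nonspecific siRNA (z = 5.50). This 7-mer was picked from the same scan, and both comparisons use the same nonspecific libraries with opposite sign. Variation of those libraries alone could give both values, so z = -7.67 is no independent support for silencing by the nonspecific siRNA. The mean of the NRAS siRNAs minus DMSO, which leaves those libraries out, gave z = -0.939. Genes carrying TGACGTA thus did not rank higher with the NRAS siRNAs than in DMSO. These groups also differ in transfection, vehicle and collection time, and a shift from those could hide a response. The value therefore cannot decide whether these genes respond to the NRAS siRNAs. Part of the rise seen against the nonspecific siRNA may belong to the control.

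For the 1078 genes that responded differently, a single response of smaller size with the siRNAs was tested by scaling the ERK inhibitor response by 21 factors from 0 to 1. The fewest genes left past the threshold were 175, at a factor of 0.4. A single response simulated at a scale of 0.4 left 1 at its fewest. The simulation held no effects of the siRNAs outside that response. In the data NRAS itself stood at -2.27 with the siRNAs and -0.10 with the inhibitor, and 63 genes differed between both siRNAs. Some genes therefore had to remain at any factor. The 175 genes show that 1 exactly scaled response does not cover every gene, but cannot exclude a scaled response beside such effects. At a factor of 1, which is the interaction test itself, the count was 1078. Between the control groups, which differ in transfection, siRNA, vehicle and collection time, 56 genes changed, and which of these is behind them was not tested. Transfection and collection time cannot be told apart from the target, since no arm separates them. A biological difference between loss of NRAS and block of ERK stays open as well, untested.

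The near absence of MYOD1, MYOG, MYF5 and MYF6 in cells of muscle tumour origin was weighed last. Of these 4 regulators 0 exceeded 1 CPM in any library, which another cell line, or a culture that lost its muscle identity, could produce. A failure of counting at these genes alone is also possible: the sarcomere list had a median of 0.104 CPM in DMSO libraries, but rhabdomyosarcoma cells can hold the regulators without those genes, so the value decides nothing. Neither explanation was excluded, because no independent measure of identity was used here, and no biological explanation was tested.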

How the results depend on the processing

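The alternatives were set before the data were examined, and no tests in this part were chosen only after the result was seen; where the cause of a shift is not evident from the setting itself, the cause was not tested. Of 230 values of named genes 215 passed the threshold, 0 of these changed sign under any setting that gave them a value, and 103 kept the call under all such settings, or 167 when the removal of replicates is set aside. Some had no value under the stricter filter, and the interaction had none in a fit of only the groups compared. Apart from genes fixed by name, the named genes were chosen for passing in the main fit. Those with the greatest rises and falls also had treated libraries on 1 side of both control libraries. The 215 passing values and the absence of sign changes therefore follow in part from that choice. Depth limits genes near 3 counts, such as MYOD1 and MYF5, for which no direction can be given. RLE and upper-quartile scaling, limma-voom and the stricter filter moved none of the called counts over 1.5 times. The balance of higher and lower calls with the ERK inhibitor, 1948 and 2180 in the main fit, was 2033 and 2034 with RLE and 2210 and 1725 with upper-quartile scaling, so that which side holds more genes depends on the scaling. Genes that did not pass changed sign in a few settings: with upper-quartile scaling MYC was at 0.00457 with the ERK inhibitor; without nonspecific replicate 2 MYH3 was at 0.052, CDKN1C at -0.12 and ERBB3 at -0.062 with the siRNAs; CDKN1C was at -0.0083 without siRNA 1 replicate 1, MYC at 0.13 without DMSO replicate 2 and NRAS at 0.017 without ERK inhibitor replicate 1, the last 2 with the inhibitor. As single libraries were left out, MYH3 ranged from -0.22 to 0.052, CDKN1C from -0.12 to 0.39 and ERBB3 from -0.062 to 0.55 with the siRNAs, and MYC from -0.20 to 0.13 with the inhibitor.

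Counts are given in the order siRNA 1, siRNA 2, siRNA 1 against siRNA 2, nonspecific siRNA against DMSO, both siRNAs, and both siRNAs with the ERK inhibitor. DESeq2 gave 763, 1651, 144, 370, 585 and 376. A fit of only the groups compared, with fewer degrees of freedom, gave 45, 225, 28, 12, 35 and 29, and 425 for the mean of the siRNAs. A required absolute log2 fold change of 1 gave 96, 210, 12, 10, 68 and 53, with 212 for the mean, 1236 for the ERK inhibitor and 502 for the interaction. No filter gave 785, 1690, 283, 611 and 411 (siRNA against siRNA moved under 1.5 times), 1765 for the mean, and a correlation of 0.189 between both responses. With an estimated correlation 0 lists passed camera for the siRNAs, and fry called 5; 2 passed for the ERK inhibitor, and fry called 16.

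The replicate block gave 1280, 2815, 120, 446, 1028 and 710 in that order, 2846 for the mean of the siRNAs and 2379 for the interaction. It changed no other count over 1.5 times and ended no call of a named gene, adding 5. Replicate numbers correlated at r = 0.0737 to 0.448 over 10 pairs of groups, and the third principal component (8.58% of the variance) put replicate 1 below replicate 2 in 5 of 5 groups, as a hint from the data of an effect shared by number. Each group has only 2 numbers, 1 correlation was under 0.1 and the labels do not say that numbers pair libraries, so the libraries were treated as sharing only a number.

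Leaving out 1 library in turn gave 28 to 374 genes for siRNA 1, 53 to 1144 for siRNA 2, 131 to 1491 for their mean, 1875 to 4392 for the ERK inhibitor, 6 to 54 for siRNA 1 against siRNA 2, 343 to 915 for the interaction, 6 to 31 for the control groups, 27 to 290 for both siRNAs and 18 to 207 for both with the inhibitor. NRAS ranged from -2.35 to -2.07 with siRNA 1, -2.44 to -2.15 with siRNA 2 and -0.23 to 0.017 with the inhibitor, the correlation of responses from 0.408 to 0.525, and the lists from 6 to 11 and from 11 to 15. Libraries whose removal moved a count over 1.5 times were, for siRNA 1, nonspecific replicates 1 (81) and 2 (133), siRNA 1 replicates 1 (28) and 2 (165) and both ERK inhibitor libraries (186 each). For siRNA 2 they were nonspecific replicates 1 (130) and 2 (465) and siRNA 2 replicate 1 (53), and for the mean nonspecific replicates 1 (131) and 2 (402), siRNA 1 replicate 1 (402) and siRNA 2 replicate 1 (377). The ERK inhibitor count moved without DMSO replicate 2 (1924) and drug replicate 1 (1875). The interaction moved without nonspecific replicate 1 (480), siRNA 1 replicate 2 (594), siRNA 2 replicate 1 (660), DMSO replicates 1 (464) and 2 (359) and drug replicate 1 (343). For siRNA 1 against siRNA 2 the counts were 18 and 6 without siRNA 1 replicates 1 and 2, 6 and 8 without those of siRNA 2, and 40 without either drug library. For the control groups they were 10 and 8 without the nonspecific replicates, 31, 25, 30 and 29 without those of siRNA 1 and siRNA 2, 12 and 6 without those of DMSO, and 20 and 19 without those of the drug. Genes changed by both siRNAs were 52 and 108 without the nonspecific replicates, 27 and 144 without those of siRNA 1, 32 without siRNA 2 replicate 1, and 145 and 146 without those of the drug. With the ERK inhibitor as well, these became 36, 78, 18, 113, 19, 98 and 98. The list count for the siRNAs rose to 11 without nonspecific replicate 1.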

Other observations

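No explanation of the values was tested in this part. The scan of 7-mers in the last paragraph of this part was chosen only after the result was seen.

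Interferon-response genes moved both ways. Their list passed camera with siRNA 1, lower at adjusted p = 0.0304, but not with siRNA 2 (adjusted p = 0.834), the mean of both (0.266) or the ERK inhibitor (0.258). It passed in the interaction, lower at adjusted p = 0.0178; siRNA 1 and the interaction had adjusted p = 0.675 and 0.579 with an estimated correlation. IFI44L rose by 1.30 (SE 0.28) with the mean of the NRAS siRNAs and by 4.32 (SE 0.33) with the ERK inhibitor, whereas ISG15, a ubiquitin-like interferon product, fell by 0.91 (SE 0.16) with the siRNAs and stood at 0.16 (SE 0.19) with the inhibitor. TRIM22, a further interferon-induced gene, had 49 counts with the inhibitor and 3 in DMSO, a ratio of 14.4 (counting interval 4.65 to 72.3). Of 31 tested members 6 were higher and 4 lower with the inhibitor, and the same adjusted over the list alone. In the BCL2 family, BMF, a cell death activator, rose in both comparisons, at 1.07 (SE 0.22) and 2.26 (SE 0.26), and PMAIP1, which encodes the cell death activator NOXA, fell in both, at -0.92 (SE 0.17) and -2.01 (SE 0.21). BBC3, which encodes PUMA, and BOK rose with the inhibitor, at 1.20 (SE 0.25) and 1.28 (SE 0.10).

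PRRX1, a mesenchymal transcription factor, rose by 0.94 (SE 0.13) with the siRNAs and by 2.12 (SE 0.15) with the inhibitor, and ID3, an inhibitor of bHLH factors, by 0.63 (SE 0.12) and 1.08 (SE 0.14). SOX9, a cartilage regulator, fell by 0.69 (SE 0.09) and 0.91 (SE 0.10), and LPL, which encodes lipoprotein lipase, by 1.32 (SE 0.23) and 1.87 (SE 0.29). With the ERK inhibitor the NOTCH ligand DLL1 rose by 1.43 (SE 0.34) and the NOTCH glycosyltransferase LFNG by 1.19 (SE 0.17), while the NOTCH1 receptor fell by 0.69 (SE 0.14) with the siRNAs. Basement membrane collagens COL4A1 at -0.47 (SE 0.10) and COL4A2 at -0.51 (SE 0.08) and the matrix protein TNC at -0.56 (SE 0.13) fell with the siRNAs. The cytokine genes IL1A and IL1B had 4 and 3 counts with the inhibitor against 120 and 142 in DMSO, ratios of 34.0 (12.9 to 127) and 53.6 (18.0 to 263) in favour of DMSO. NF-kB and cytokine genes did not pass as a list with the inhibitor (camera adjusted p = 0.0972). Markers of other lineages went both ways with the inhibitor: the neuronal gene SNAP25 rose by 1.16 (SE 0.18), the neurofilament gene NEFM fell by 2.60 (SE 0.31), and the endothelial receptor KDR had 2 counts against 23.

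In the same scan of 3' UTRs, genes carrying GCACTTT (z = 9.80) or GTGCAAT (z = 8.27) were higher with the nonspecific siRNA than in DMSO. These sequences pair with the seeds of the miR-17 and miR-25 families of microRNAs. For the ERK inhibitor no 7-mer exceeded the 95th percentile of the permuted highest absolute z, 4.59.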
